A study of Mus musculus with 6 samples.

How the data were processed

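Expression was measured on 6 microarrays that carry RNA from the surface epithelium of C57BL/6 mouse airways, sorted into basal, ciliated and club cells, with 2 arrays of each cell type. Per the labels' protocols, the cells were stained with antibodies to EpCAM, SSEA1 and CD24 and with the lectin GSIβ4, and sorted by flow cytometry. All gates required EpCAM. Basal cells were in addition positive for GSIβ4, secretory (club) cells for SSEA1, and ciliated cells were negative for GSIβ4 and positive for CD24. Total RNA was extracted with Trizol, labelled with biotin and handled by the Affymetrix protocol, per the labels' protocols. The array platform and the genome build are not given in the sources used here. The labels call the arrays of a cell type biological replicates and do not say which animals they came from, so the p-values rest on the spread between these samples.

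The submitters' processing notes name RMA, a method that corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set on a log2 scale; no version is given. The deposited log2 values come in a matrix of 35556 probe sets and in a table of 1 value per gene symbol and array, which the authors call aggregate expression per the file headers. The per-gene table was checked against the matrix. Of its cells, 100 percent equalled a probe set of the same array within 1e-06 log2 units. In 20079 genes, 1 probe set supplied all 6 values, and in 236 genes different arrays took different probe sets. The table held 20315 named genes. Its 1 further line had no symbol, equalled the maximum of the array in 6 of 6 columns and was left out. The authors also deposited a score of enrichment per gene and cell type, a z-score per the file headers. It equalled the mean of the cell type minus the mean of the 6 arrays, divided by the SD of the 6 arrays over the square root of the number of replicates, within 9.34e-14. A table of 50 genes with their basal z-score was used as deposited, and 18 columns of another study beside them were not used. No detection calls are given, so no gene could be called absent, and the precision is limited by the number of arrays.

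The design fixed before the data were examined assumed probe sets that carry gene symbols. Since no table used here pairs probe sets with genes, the tests were run on the authors' per-gene log2 values without further normalization and without a filter on dim genes. Gene names are those of the deposited table. Of these, 19535 were current symbols and 605 more were synonyms of 1 gene in the RefSeq gene table of mouse assembly GRCm38.p6, which was used for names alone. One linear model with a mean per cell type was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, and the variances were moderated by empirical Bayes (prior SD 0.1877, prior degrees of freedom 4.297, total degrees of freedom 7.297). The contrasts were ciliated minus basal, club minus basal and ciliated minus club. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the contrast. A gene counted as higher in a cell type than in both others when both contrasts passed and the smaller difference was at least 1 log2 unit. Levels are given as mean ± SD over 2 arrays and differences as log2 difference ± standard error of the fit, and every adjusted p of a gene comes from this limma fit.

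Gene lists were fixed before the data were examined: markers of basal, club, ciliated, goblet, serous, myoepithelial, tuft, neuroendocrine and alveolar type 2 cells, ionocytes, leukocytes, fibroblasts, endothelial cells, chondrocytes and erythroid cells, the sort antigens, and lists for hemidesmosomes, extracellular matrix, xenobiotic metabolism, mucosal defence, the secretory pathway, multiciliogenesis, axonemal dyneins, radial spokes and the central pair, intraflagellar transport, oxidative phosphorylation, ribosomal proteins, the cell cycle, Notch, Wnt and epidermal growth factor receptor signalling, ion transport, the dissociation and heat-shock response, interferon-stimulated genes and MHC class II. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 34 lists per contrast. Camera asks whether the members moved more than the other genes. Camera with an estimated correlation and fry, which asks whether the members on balance moved one way, were run beside it. The erythroid list had 3 measured members and was not tested.

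The genes named in the text follow a rule set before the data were examined. They are the 10 largest called differences in each direction of a contrast whose arrays did not overlap, the 10 genes with the largest smaller difference for each cell type, the 4 members of each list with the largest difference in a contrast, and the 5 sort antigens; predicted and unnamed gene models were passed over. Other genes are named as chosen after their values were seen. The alternatives were quantile normalization applied again, centring each array on its median, cyclic loess, leaving out dim genes, testing every probe set, an intensity trend and a robust fit of the variances, a fit of 4 arrays alone, stricter thresholds, the replicate number as a block, the authors' z-scores and leaving out each array in turn. A block for array sets was added after seeing the data.

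The fit and the list tests were tested on simulated data. Values of 20315 genes were drawn from their observed means and the fitted distribution of variances, independently of each other and with the same spread in every cell type. In each contrast 100 genes were changed 2-fold and 100 genes 4-fold. In ciliated minus basal, 21 percent of the 2-fold and 93 percent of the 4-fold changes were recovered, with 5 false calls among 119. In club minus basal these were 29 and 91 percent, with 6 false calls among 126. In ciliated minus club they were 27 and 93 percent, with 14 false calls among 134, more than the threshold aims at. The data gave 3570, 1629 and 3126 calls in these contrasts, so the Benjamini-Hochberg cut-off on the unadjusted p was stricter in the simulation. The recovered shares therefore do not give the sensitivity of the fit on the data. With no change simulated, 0 genes were called by limma in any contrast. A planted list of genes raised 2-fold was found by camera in each contrast, and 0 of the 34 other lists were called. Because the simulated genes were independent, this does not check camera on correlated lists. The common spread likewise leaves the error rate against the more variable basal arrays unchecked. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.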

Results

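The surface epithelium of the mouse airway is made up mainly of basal cells, which lie on the basement membrane and act as progenitors, of secretory club cells and of multiciliated cells. RNA of these 3 sorted populations was profiled on 6 arrays, 2 per cell type, and the design asks how their expression differs. All levels below are RMA log2 values of the authors' per-gene table, so that 1 unit is a 2-fold difference. The arrays were alike in scale: the median over all probe sets lay between 6.35 in club replicate 2 and 6.48 in ciliated replicate 1, and the maximum between 14.76 and 14.94. Across genes, which are not independent replicates, the Pearson correlation was 0.989 between the ciliated arrays, 0.987 between the club arrays and 0.974 between the basal arrays. It ranged from 0.936 to 0.953 for basal against club arrays, from 0.904 to 0.915 for ciliated against club and from 0.883 to 0.894 for basal against ciliated. The basal arrays differed from each other by more than 1 log2 unit in 613 genes, the ciliated arrays in 100 and the club arrays in 193, so basal levels carried the widest replicate error. The fit gives the cell types a common spread per gene, so p-values against basal cells may be too small. With 2 arrays per cell type, the number of arrays limits the precision of every difference.

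The transcripts behind the sort antigens were looked at first, as a check of the gates and not as a finding. Ggta1, whose enzyme makes the galactose epitope that GSIβ4 binds, stood at 9.13 ± 0.29 in basal cells (SD, n = 2), against 6.20 ± 0.17 in ciliated and 6.29 ± 0.06 in club cells. Fut9, a fucosyltransferase that makes the SSEA1 carbohydrate, was at 7.46 ± 0.32 in club cells, 5.30 ± 0.06 in ciliated and 4.68 ± 0.09 in basal cells, while Fut4, of the same family, was at 5.18 to 5.40 in all 3. Both the Ggta1 differences from basal and the Fut9 differences from club passed the test (limma adjusted p at most 0.00031). Cd24a was at 13.49 ± 0.13 in ciliated, 12.97 ± 0.30 in club and 11.29 ± 0.86 in basal cells. The contrast Cd24a, ciliated minus basal, passed with all arrays (2.19 ± 0.37, adjusted p = 0.0058) and ended without ciliated replicate 1 (adjusted p = 0.059) or ciliated replicate 2 (adjusted p = 0.0503). The contrast Cd24a, club minus basal, also passed (1.67 ± 0.37, adjusted p = 0.037) and ended under several alternatives, among them a renewed quantile normalization, cyclic loess and leaving out either ciliated or either club array. Epcam, required in every gate, was at 9.32 ± 0.54 in basal, 10.07 ± 0.06 in ciliated and 9.96 ± 0.04 in club cells and passed in no contrast over all genes. As a list of 5, the sort antigens had 1 up and 1 down in ciliated minus basal, 2 up and 1 down in club minus basal and 1 down in ciliated minus club (3 and 1, 3 and 1, and 0 and 1 adjusted over the list alone), and did not shift (camera adjusted p = 0.51 in ciliated minus basal, 0.22 in club minus basal and 0.63 in ciliated minus club). Their median and mean differed in sign in ciliated minus club (0.111 and -0.277), and camera and fry differed in direction in ciliated minus basal.

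Ciliated cells differed from basal cells above all in the genes of the motile cilium. Cdhr4, a cadherin-related gene, stood at 13.48 ± 0.01 in ciliated cells and 6.45 ± 0.09 in basal cells (SD, n = 2 each), a 131-fold difference. Sntn, which encodes a protein of the ciliary tip, was at 12.67 ± 0.22 against 5.84 ± 0.50. In the other direction, the basal keratin Krt5 was at 13.09 ± 0.21 in basal and 8.59 ± 0.97 in ciliated cells, a 22.6-fold difference. Defb1, a beta-defensin, was at 11.03 ± 0.37 in basal and 5.64 ± 0.19 in ciliated cells, the largest fall in log2 value among all genes tested. Each of the 4 differences exceeded the replicate spread (limma adjusted p at most 0.00024).

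Most members of the lists for axonemal dyneins, radial spokes and the central pair, intraflagellar transport and ciliated cell markers rose. Of 29 axonemal dynein and dynein assembly genes, 27 rose and 2 did not pass, with a median difference of 3.81 log2 units. The heavy chains Dnah5 (5.95 ± 0.20, SE), Dnah6 (6.38 ± 0.21) and Dnah9 were among them, Dnah9 at 11.88 ± 0.01 against 6.23 ± 0.07. Of 24 genes of the radial spokes and central pair, 23 rose (median 4.46), led by Spag6l of the central pair (6.55 ± 0.21), the radial spoke head gene Rsph4a (6.48 ± 0.20) and Hydin (6.05 ± 0.21). The trains and the BBSome that carry cargo along the axoneme rose in 34 of 35 members by a smaller median of 2.15, with Ift88 at 3.01 ± 0.16 and Bbs1 at 2.25 ± 0.24. All 20 ciliated cell markers rose (median 4.26), including the dynein light chain Dynlrb2 (5.47 ± 0.15). Adjusted over the list alone, 27 dynein, 24 radial spoke, 34 transport and 20 marker genes rose. Camera gave adjusted p values of 3.4e-32 for the dyneins, 8e-32 for the radial spokes, 4.7e-28 for the transport genes and 4.3e-25 for the markers. These lists gave an adjusted p = 0.093, 0.078, 0.093 and 0.13 with an estimated correlation, so none was called that way.

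Among regulators of multiciliogenesis, 8 of 18 rose and 10 did not pass (median 0.527; 10 rose adjusted over the list alone; camera adjusted p = 5.7e-05, and adjusted p = 0.16 with an estimated correlation). Foxj1, the transcription factor of motile ciliogenesis, was at 10.73 ± 0.59 against 7.73 ± 0.15, and Trp73, Rfx3 and Myb were higher by 2.77 ± 0.21, 2.38 ± 0.19 and 2.20 ± 0.17. Mcidas and Ccno, which act early and briefly in the commitment to many cilia, are named here after their values were seen: Mcidas was at 7.60 ± 0.09 in ciliated and 7.59 ± 0.06 in basal cells, and Ccno at 8.54 ± 0.41 and 8.37 ± 0.32.

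The genes that anchor a cell to the basement membrane were lower in ciliated cells. Of 18 basal cell markers, 17 fell, with Krt5, the basal transcription factor Trp63 (lower by 3.99 ± 0.20) and the water channel Aqp3 among them. The exception, named after its value was seen, was the tetraspanin Tspan1, at 11.15 ± 0.20 in ciliated and 8.87 ± 0.35 in basal cells. In the hemidesmosome and laminin-332 list 8 of 11 fell, including the laminin chain Lamb3 (11.28 ± 0.03 in basal, 7.28 ± 0.13 in ciliated cells) and Col17a1 (10.15 ± 0.03 and 7.26 ± 0.14). Of 20 other matrix and integrin genes, 10 fell and 10 did not pass, with the matricellular protein gene Sparc lower by 3.77 ± 0.18. Adjusted over the list alone, 17, 9 and 11 members fell, and 1 basal marker rose. The medians were lower by 3.03, 1.08 and 0.746, with camera adjusted p values of 7.9e-14, 2.1e-07 and 0.00016. The same lists had an adjusted p = 0.1, 0.13 and 0.3 with an estimated correlation. Dcn and Fbln1, proteoglycan and fibulin genes that fibroblasts express strongly, moved with this group: Dcn was at 12.21 ± 0.12 in basal and 7.34 ± 0.98 in ciliated cells, and Fbln1 at 9.33 ± 0.23 and 7.03 ± 0.08. The collagen gene Col1a2 was at 7.13 ± 0.09 and 7.08 ± 0.14.

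Genes of growth and translation were lower in ciliated cells too. Of 30 ribosomal protein genes, 25 fell (27 adjusted over the list alone), by a median of 1.15, with Rps18 at 10.35 ± 0.12 against 12.33 ± 0.19 in basal cells (camera adjusted p = 1.6e-16, and adjusted p = 0.13 with an estimated correlation). Of 29 cell cycle genes, 21 fell and none rose (28 fell adjusted over the list alone). Mki67, the proliferation antigen, was lower by 1.94 ± 0.21 and the mitotic kinase gene Plk1 by 1.51 ± 0.18. The list's camera adjusted p was 1.3e-12, with an adjusted p = 0.13 with an estimated correlation. Of 42 oxidative phosphorylation genes none passed in limma, over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05 (median 0.0365, camera adjusted p = 0.65). Without basal replicate 2 that list shifted up (median 0.262, adjusted p = 0.017).

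Some secretory genes were higher in ciliated than in basal cells. Of 17 club cell markers 6 rose and 1 fell, and adjusted over the list alone 6 rose and 2 fell (median 0.354, camera adjusted p = 0.0054, and adjusted p = 0.52 with an estimated correlation). Nupr1, a stress-responsive chromatin protein gene, rose by 3.37 ± 0.23, and the lectin gene Reg3g and the retinal dehydrogenase gene Aldh1a1 by 1.84 ± 0.17 and 1.58 ± 0.18. The call for this list ended without ciliated replicate 1 (median 0.242, adjusted p = 0.072) and with cyclic loess (median 0.275, adjusted p = 0.23). Of 14 goblet cell genes 4 rose, also over the list alone, among them Agr2 of the mucin-folding machinery (1.28 ± 0.22; camera adjusted p = 0.0096, and adjusted p = 0.33 with an estimated correlation). Xenobiotic enzymes went both ways: of 28, 6 rose and 4 fell (7 and 7 adjusted over the list alone; median 0.0947, camera adjusted p = 0.63). The cytochromes Cyp2b10 (2.83 ± 0.16) and Cyp2s1 (1.92 ± 0.18) were higher in ciliated cells, and Fmo2 and Aldh3a1 were lower by 2.28 ± 0.18 and 2.21 ± 0.26. Of 18 mucosal defence genes 7 rose, with the immunoglobulin receptor gene Pigr at 10.40 ± 0.24 against 8.01 ± 0.06, and 2 fell, Defb1 among them (the same counts adjusted over the list alone; camera adjusted p = 0.18). The secretory pathway had 6 of 24 up and 2 down by either adjustment, adjusted over the list alone included (camera adjusted p = 0.2), with the coat protein gene Sec24d higher by 1.29 ± 0.18.

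Interferon-stimulated genes were higher in ciliated cells. Of 18, 8 rose and none fell (11 rose adjusted over the list alone), with Oas2, a sensor of double-stranded RNA, at 9.98 ± 0.13 against 6.58 ± 0.04 and Ifit3 and Usp18 higher by 2.72 ± 0.28 and 2.12 ± 0.30. The median was 0.675 (camera adjusted p = 2.1e-05, and adjusted p = 0.21 with an estimated correlation). MHC class II genes went the other way: 4 of 7 fell, also adjusted over the list alone (median lower by 2.13), with H2-Aa at 8.74 ± 0.65 in basal and 5.80 ± 0.27 in ciliated cells and H2-Eb1 at 9.26 ± 0.02 and 7.13 ± 0.46 (camera adjusted p = 0.01, and adjusted p = 0.4 with an estimated correlation). The leukocyte gene Laptm5 moved with them, lower by 1.34 ± 0.16. The dissociation and heat-shock list shifted up, with 2 of 22 rising and 1 falling (4 and 1 adjusted over the list alone; median 0.485, camera adjusted p = 0.0045, and adjusted p = 0.45 with an estimated correlation), and the chaperone gene Hsph1 was higher by 2.42 ± 0.17. That call ended with quantile normalization applied again (median 0.131, adjusted p = 0.32), with cyclic loess (median 0.208, adjusted p = 0.32) and without basal replicate 2 (median 0.202, adjusted p = 0.14).

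In total, 3570 of 20315 genes (17.6 percent) differed between ciliated and basal cells, 1888 higher and 1682 lower in ciliated cells, and 2361 of them by at least 2-fold. The balance depended on scaling: 52.9 percent were higher in ciliated cells here, 48.4 percent with quantile normalization applied again and 58 percent with cyclic loess. The count was 2196 without ciliated replicate 1 and 1907 without ciliated replicate 2. Of the 34 lists, 17 shifted by camera (10 up, 7 down), 16 by fry and 0 by camera with an estimated correlation, where 9 had an unadjusted p under 0.05. Fry did not call the club marker and dissociation lists that camera called, and called the fibroblast list that camera did not.

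Club cells were set apart from basal cells by secreted and defence proteins. Muc5b, a gel-forming airway mucin, stood at 13.47 ± 0.30 in club and 8.43 ± 1.0 in basal cells (SD, n = 2 each), a 32.8-fold difference. Pigr, which carries immunoglobulin A across the epithelium, was 24.6-fold higher (12.63 ± 0.08 against 8.01 ± 0.06), and the iron-sequestering lipocalin Lcn2 22.2-fold. The sulfotransferase gene Sult1c1 was at 10.74 ± 0.08 in club cells and at 5.14 ± 0.53 in basal cells, a level near the lower quartile of the probe sets in the basal arrays (5.14 and 5.10), so no exact fold is given for it. Krt5 was 16.2-fold lower in club cells, at 9.08 ± 0.27 (limma adjusted p at most 0.0014 for each of the 5).

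Of 17 club cell markers, 14 rose and 3 did not pass, with a median of 1.68 (15 rose adjusted over the list alone; camera adjusted p = 4.9e-16, and adjusted p = 0.16 with an estimated correlation). Nupr1 was higher by 3.61 ± 0.23, and the plasma protein genes Hp and Pon1 by 3.21 ± 0.27 and 3.21 ± 0.28. The secretoglobin Scgb1a1 and Cyp2f2, club cell genes named after their values were seen, were near the top of the scale in every cell type: Scgb1a1 was at 14.14 in club, 14.04 in ciliated and 13.04 in basal cells, and Cyp2f2 at 14.48, 14.45 and 14.30. Of 18 mucosal defence genes 11 rose and 2 fell (12 and 2 adjusted over the list alone; median 1.7), with the surfactant collectin Sftpa1 at 12.92 ± 0.23 against 9.13 ± 0.23. Of 14 goblet cell genes 7 rose, also adjusted over the list alone (median 0.854), including the secretory-cell gene Clca1 (3.97 ± 0.47), the trefoil factor Tff2 (2.66 ± 0.26) and Agr2 (2.40 ± 0.22). The mucin Muc5ac, a goblet cell product, was at 8.41 ± 0.43 against 6.14 ± 0.06. Camera's adjusted p was 4e-06 for defence and 2.8e-07 for goblet genes. Each list had an adjusted p = 0.16 with an estimated correlation.

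Enzymes and transporters rose alongside. Of 28 xenobiotic enzymes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.565), among them Ces1f (2.87 ± 0.32), the flavin monooxygenase gene Fmo1 (2.65 ± 0.32) and Cyp2b10 (2.23 ± 0.16). Cyp2s1 fell, by 2.77 ± 0.18. Of 20 ion transport genes 9 rose and none fell (10 rose adjusted over the list alone; median 0.619), with the sodium-proton exchanger Slc9a4 (2.68 ± 0.15), the potassium channel Kcnq1 (2.50 ± 0.24) and the bicarbonate cotransporter Slc4a4 (2.48 ± 0.24) leading. The secretory pathway list shifted by a median of 0.535, with 3 of 24 past the test over all genes and 10 adjusted over the list alone. Its largest change was in Creb3l1, a transcription factor of secretory capacity, at 10.30 ± 0.43 against 7.22 ± 0.30. Camera gave adjusted p values of 3.9e-08, 8.2e-07 and 8.2e-07 for the 3 lists, all with an adjusted p = 0.16 with an estimated correlation.

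Basal genes were lower in club cells. Of 18 basal markers 14 fell, by a list median of 2.69, with Trp63 at 7.14 ± 0.16 against 10.93 ± 0.04, and Tspan1, chosen after its values were seen, rose by 1.72 ± 0.26. In the hemidesmosome list 6 of 11 fell (median lower by 1.01), with Lamb3, Col17a1 and the integrin chain Itgb4 lower by 3.80 ± 0.15, 3.05 ± 0.15 and 2.29 ± 0.18. In the matrix list 8 of 20 fell (median lower by 0.49), with Sparc lower by 3.57 ± 0.18. Adjusted over the list alone, 14, 9 and 9 fell. Camera's adjusted p was 4e-13, 1.4e-08 and 0.00011, and the lists had an adjusted p = 0.16, 0.16 and 0.21 with an estimated correlation. Here too Dcn and Fbln1 moved with the basal genes, lower in club cells by 4.42 ± 0.41 and 2.66 ± 0.17. Of 29 cell cycle genes, 6 fell (14 adjusted over the list alone; median lower by 0.71, camera adjusted p = 7.9e-08, and adjusted p = 0.16 with an estimated correlation). Of 30 ribosomal protein genes 2 fell by either adjustment, adjusted over the list alone included, while the list shifted down by 0.395 (camera adjusted p = 5.1e-06, and adjusted p = 0.23 with an estimated correlation).

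A minority of cilia genes passed between club and basal cells, and of the cilia lists fry called only the radial spokes. Of 24 radial spoke and central pair genes 5 rose (8 adjusted over the list alone; median 0.351, camera adjusted p = 8.4e-06, and adjusted p = 0.16 with an estimated correlation). Of 20 ciliated cell markers 1 rose by either adjustment, adjusted over the list alone included: Sec14l3, at 12.56 ± 0.11 against 10.65 ± 0.53 (median 0.37, camera adjusted p = 9e-04, and adjusted p = 0.4 with an estimated correlation). Of 29 dynein genes 3 rose (4 adjusted over the list alone; median 0.132, camera adjusted p = 0.004, and adjusted p = 0.34 with an estimated correlation). The dynein heavy chain gene Dnah12 was at 8.40 ± 0.94 in club, 5.92 ± 0.17 in basal and 11.97 ± 0.42 in ciliated cells. None of 35 intraflagellar transport genes passed in limma, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05, though the list shifted by 0.109 (camera adjusted p = 0.047, and adjusted p = 0.45 with an estimated correlation). Without basal replicate 1 the median was 0.0432 and the call ended (adjusted p = 0.46). The call also ended at similar medians without club replicate 1 (0.104, adjusted p = 0.11) or club replicate 2 (0.127, adjusted p = 0.076) and with cyclic loess (0.145, adjusted p = 0.075). At the same median of 0.109 it ended without dim genes (adjusted p = 0.19), with an intensity trend (0.072) and with the replicate block (0.066). Without basal replicate 1 the marker call ended at a smaller median (0.166, adjusted p = 0.12) and the dynein call at a slightly larger one (0.165, adjusted p = 0.066). Of 18 multiciliogenesis genes 2 rose by either adjustment, adjusted over the list alone included (camera adjusted p = 0.1). Gmnc, which starts the multiciliated program, was at 9.17 ± 0.43 in club cells against 6.59 ± 0.04 in basal cells (2.58 ± 0.25, adjusted p = 0.0011), whereas Foxj1 was at 7.84 ± 0.06 and 7.73 ± 0.15.

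Interferon and MHC class II genes again moved apart. Of 18 interferon-stimulated genes 5 rose (11 adjusted over the list alone; median 0.638, camera adjusted p = 6.5e-07, and adjusted p = 0.16 with an estimated correlation), with Oas2 and Ifi44 higher by 2.78 ± 0.15 and 2.62 ± 0.24. Of 7 class II genes 4 fell, also adjusted over the list alone (median lower by 2.43, camera adjusted p = 0.00011, and adjusted p = 0.2 with an estimated correlation), with H2-Ab1 at 6.33 ± 0.21 against 8.95 ± 0.07 in basal cells, and Laptm5 was lower with them by 1.43 ± 0.16. The dissociation and heat-shock list rose by a median of 0.579, with 2 of 22 past the test, also adjusted over the list alone (camera adjusted p = 4.6e-06, and adjusted p = 0.21 with an estimated correlation). None of 42 oxidative phosphorylation genes passed in limma, and none had an unadjusted p under 0.05 (camera adjusted p = 0.44), but without basal replicate 2 that list shifted up (median 0.233, adjusted p = 0.00068).

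Fewer genes passed here than in the comparisons with ciliated cells: 1629 of 20315 (8.02 percent), 884 higher and 745 lower in club cells, 1131 of them by at least 2-fold. The share higher in club cells was 54.3 percent, and 62.4 percent with arrays centred on the median. The count depended on the arrays used. The fit of only the 4 basal and club arrays gave 1050, with the same differences and another estimate of the spread. Leaving out either ciliated array gives that same fit for this contrast, since a lone array adds nothing to the spread. Counts without a basal or club array are given further below. Of the 34 lists, 23 shifted by camera (15 up, 8 down), 19 by fry and 0 by camera with an estimated correlation (10 at an unadjusted p under 0.05). The lists called by camera and not by fry were ciliated markers, dyneins, transport, dissociation, tuft cells and ionocytes, and those called by fry alone were the leukocyte and myoepithelial lists.

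Between the differentiated types, ciliated cells again led in the genes of the axoneme and club cells in secretion. Cdhr4 was at 13.48 ± 0.01 in ciliated and 7.28 ± 0.07 in club cells (SD, n = 2 each), a 74.0-fold difference, and Hydin, Spag6l and Rsph4a were higher by 5.69 ± 0.21, 5.83 ± 0.21 and 5.55 ± 0.20 (SE). Kcnmb1, a subunit of the large-conductance potassium channel, was at 11.45 ± 0.10 in ciliated, 5.84 ± 0.11 in club and 6.12 ± 0.41 in basal cells. The amino acid transporter Slc6a15 was 13.7-fold higher in club cells, at 10.24 ± 0.08 against 6.47 ± 0.21, and the collagen cross-linking enzyme gene Lox was higher there by 3.64 ± 0.24. Each passed the test (limma adjusted p at most 6.3e-05).

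All 20 ciliated markers, 27 of 29 dynein genes, 23 of 24 radial spoke genes and 32 of 35 transport genes were higher in ciliated cells, with medians of 4.16, 3.73, 4.15 and 2.04. Adjusted over the list alone, 20, 27, 24 and 33 rose. Camera's adjusted p was 2.1e-23, 4.1e-31, 3.2e-30 and 5.3e-26, and the lists had an adjusted p = 0.26, 0.1, 0.085 and 0.1 with an estimated correlation. Of 18 multiciliogenesis genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.436, camera adjusted p = 0.012, and adjusted p = 0.37 with an estimated correlation), with Trp73 and Foxj1 higher in ciliated cells by 3.28 ± 0.21 and 2.88 ± 0.27. The gene that fell was Gmnc. The contrast Gmnc, ciliated minus club, was -1.44 ± 0.25 (adjusted p = 0.0072) and ended without ciliated replicate 1 (adjusted p = 0.0685).

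Club cells exceeded ciliated cells in 9 of 17 club markers, and no marker went the other way, also adjusted over the list alone (median 1.31 higher in club cells, camera adjusted p = 1.3e-05, and adjusted p = 0.37 with an estimated correlation). Pon1, the claudin gene Cldn10 and Hp were higher in club cells by 2.85 ± 0.28, 2.7 ± 0.27 and 2.53 ± 0.27, whereas Nupr1 was at 13.20 ± 0.34 and 12.96 ± 0.01. Of 18 defence genes 6 were higher in club cells (7 adjusted over the list alone), with Pigr higher by 2.23 ± 0.17 and Lcn2 by 2.44 ± 0.40. Of 14 goblet cell genes 7 were higher in club and 1 in ciliated cells by either adjustment, adjusted over the list alone included, and Muc5ac was higher in club cells by 1.86 ± 0.26. Of 24 secretory pathway genes 6 were higher in club cells, also adjusted over the list alone, with the endoribonuclease gene Ern2, a stress sensor of mucous cells, at 9.80 ± 0.18 against 7.43 ± 0.46. The camera adjusted p was 0.00029 for defence, 0.0069 for goblet and 0.0059 for secretory pathway genes. These had an adjusted p = 0.33, 0.37 and 0.37 with an estimated correlation.

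Of 28 xenobiotic enzymes, 10 were higher in club and 2 in ciliated cells (12 and 3 adjusted over the list alone; camera adjusted p = 8.4e-05, and adjusted p = 0.33 with an estimated correlation). Aldh3a1, Fmo1 and Ces1f were higher in club cells by 2.76 ± 0.26, 2.7 ± 0.32 and 2.69 ± 0.32. Cyp2s1 ran opposite, 25.8-fold higher in ciliated cells (13.07 ± 0.12 against 8.38 ± 0.16). Of 20 ion transport genes 8 were higher in club and 3 in ciliated cells (9 and 3 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.37 with an estimated correlation). The calcium-activated chloride channel gene Ano1 was at 11.41 ± 0.01 in club and 8.19 ± 0.55 in ciliated cells, and the carbonic anhydrase gene Car2 at 5.20 ± 0.07 and 6.85 ± 0.20. Of 30 ribosomal protein genes 17 were lower in ciliated cells (23 adjusted over the list alone; median lower by 0.744, camera adjusted p = 2.6e-12, and adjusted p = 0.31 with an estimated correlation), with Rps18 lower by 1.39 ± 0.17. Of 29 cell cycle genes 9 were lower in ciliated cells, also adjusted over the list alone (camera adjusted p = 2e-04, and adjusted p = 0.37 with an estimated correlation).

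Several functional lists did not shift between ciliated and club cells. Basal markers had 2 up and 5 down of 18 by either adjustment, adjusted over the list alone included (camera adjusted p = 0.088), with podoplanin (Pdpn) and Krt15 higher in club cells by 2.18 ± 0.21 and 1.91 ± 0.19. Without ciliated replicate 2 that list shifted down (median -0.516, adjusted p = 0.0031). Camera's adjusted p was 0.9 for hemidesmosomes, whose median (-0.0848) and mean (0.0281) differed in sign, 0.31 for the matrix, 0.44 for MHC class II (none of 7 past the limma test, 1 at an unadjusted p under 0.05), 0.63 for interferon-stimulated genes, 0.62 for the dissociation response and 0.88 for oxidative phosphorylation. In the last list, with none of 42 genes past the limma test and 3 at an unadjusted p under 0.05, the median and mean lay above 0 (0.00892 and 0.00847) while camera's direction was down.

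In all, 3126 of 20315 genes (15.4 percent) differed, 1611 higher and 1515 lower in ciliated cells, 2062 of them by at least 2-fold. Here too the balance depended on scaling, with 51.5 percent higher in ciliated cells as reported, 43.2 percent with arrays centred on the median, 48.5 percent with quantile normalization applied again and 55.7 percent with cyclic loess. The count was 1732 without ciliated replicate 1, 1587 without ciliated replicate 2 and 1879 without club replicate 1. Of the 34 lists, 15 shifted by camera (5 up, 10 down), 14 by fry and 0 by camera with an estimated correlation (5 at an unadjusted p under 0.05). Camera alone called the secretory pathway and tuft lists, and fry alone the myoepithelial list.

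Each cell type had its own set of genes above both others. By the rule of both contrasts passing and a smaller difference of at least 1 log2 unit, 966 genes were highest in ciliated, 368 in basal and 299 in club cells. The basal set was led by Defb1, Ccdc3, Dcn and Vsnl1, whose smaller differences were 5.22, 4.43, 4.42 and 4.32, followed by Trim29, Krt5, the serpin gene Serpinb5, Igfbp7, Lamb3 and Trp63. The ciliated set was led by Cdhr4 (6.21), Sntn (5.99), Spag6l (5.83) and the diamine oxidase gene Aoc1 (5.79). In club cells the first were the sialyltransferase gene St8sia6 (3.71), the lung chemokine gene Cxcl15 (3.67), Sult1c1 (3.62) and the ATPase gene Atp13a5 (3.60), and the transcription factor gene Elf5 stood at 9.45 ± 0.06 against 5.97 ± 0.26 in basal and 6.33 ± 0.18 in ciliated cells.

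**Figure D1:**
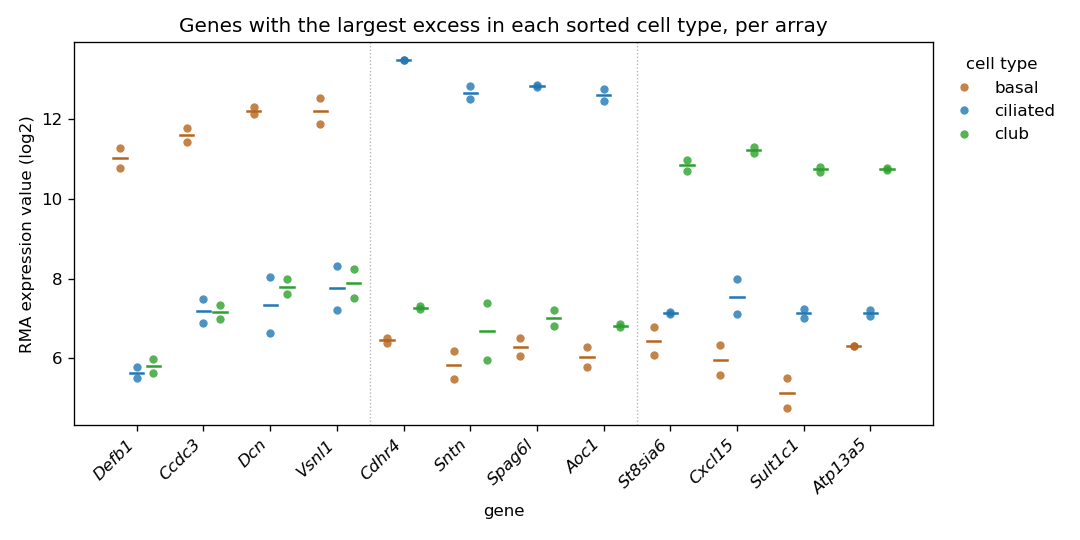
RMA log2 value (vertical axis) of the 4 genes with the largest smaller difference for each cell type, with a dot per array, a bar at the mean of 2 arrays and a colour per cell type. In each of the 12 genes both arrays of its own type lay above the 4 arrays of the other types, from Cdhr4 at 13.48 in ciliated cells to Sult1c1 at 10.74 in club cells.

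Markers of other cells that a gate could have taken up were read in the same way. None of 12 neuroendocrine, 10 endothelial and 10 chondrocyte genes passed in limma in any contrast, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were at most 1, 2 and 1 per contrast, and the camera adjusted p was 0.47 to 0.68, 0.63 to 0.82 and 0.13 to 0.63. The endothelial median and mean differed in sign in club minus basal (-0.0917 and 0.00633). The 3 measured erythroid genes, not tested as a list, did not pass in limma (at most 1 at an unadjusted p under 0.05 per contrast; median 0.251 in ciliated minus basal). Of 10 myoepithelial genes none passed in ciliated minus basal (3 at an unadjusted p under 0.05 in limma; 2 rose and 1 fell adjusted over the list alone), 1 fell in club minus basal and 1 rose in ciliated minus club (camera adjusted p = 0.58, 0.9 and 0.44). Fry called that list down in club minus basal (adjusted p = 0.035) and up in ciliated minus club (adjusted p = 0.0034). Of 9 serous gland genes 1 rose in ciliated minus basal, 2 rose in club minus basal and 1 fell in ciliated minus club (1, 3 and 2 adjusted over the list alone). In club over basal cells these were Lyz1 (3.58 ± 0.26) and Ltf (2.93 ± 0.50), the latter not without club replicate 1 or 2. The list was not called by camera (camera adjusted p = 0.32, 0.093 and 0.44 in the 3 contrasts), and its median (-0.0631) and mean (0.728) differed in sign in club minus basal. Without basal replicate 2 it shifted up there (adjusted p = 0.026). Leukocyte genes had 3 lower and 1 higher against basal cells in both contrasts, with Lyz2 higher in club cells by 2.33 ± 0.30 and Laptm5 lower (adjusted over the list alone, 3 and 4 fell and 2 and 1 rose; camera adjusted p = 0.65 and 0.092). Fry called the list down in club minus basal (adjusted p = 0.027), and without basal replicate 2 camera's adjusted p there was 0.049. In ciliated minus club 1 leukocyte gene rose (camera adjusted p = 0.44).

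Tuft cell markers, with none of 12 past the limma test and 2 at an unadjusted p under 0.05, were higher in club than in basal cells by a median of 0.297 (camera adjusted p = 0.026, and adjusted p = 0.46 with an estimated correlation), and 2 of 12 were lower in ciliated than in club cells (6 adjusted over the list alone; camera adjusted p = 0.005, and adjusted p = 0.52 with an estimated correlation). Both calls ended without club replicate 1, where the median of the first was -0.0107 (adjusted p = 0.74) and that of the second was -0.255 (adjusted p = 0.062), and the first also without basal replicate 1 (median 0.258, adjusted p = 0.087). They did not shift in ciliated minus basal (camera adjusted p = 0.2). Ionocyte markers were higher in club than basal cells by 0.473, with 1 of 10 past the test, also adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.32 with an estimated correlation). That call ended without basal replicate 1 (median 0.336, adjusted p = 0.087) or club replicate 1 (median 0.154, adjusted p = 0.17). In the other contrasts their camera adjusted p was 0.17 (1 rose) and 0.78 (none passed in limma, 1 at an unadjusted p under 0.05).

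Of 12 fibroblast genes, Dcn and Fbln1 fell in each contrast with basal cells, also adjusted over the list alone. The list shifted in club minus basal (median lower by 0.236, camera adjusted p = 0.0068, and adjusted p = 0.32 with an estimated correlation), not in ciliated minus basal (median -0.00891, mean -0.593, camera adjusted p = 0.32), where fry called it down (adjusted p = 0.029), or ciliated minus club (0.39, with none of 12 past the limma test and 1 at an unadjusted p under 0.05). Of 10 alveolar type 2 genes, 6 rose in club over basal cells (6 rose and 1 fell adjusted over the list alone; median 1.74, camera adjusted p = 9.3e-06, and adjusted p = 0.17 with an estimated correlation), among them Cxcl15 and the surfactant gene Sftpb, at 10.69 ± 0.42 against 7.87 ± 0.03. In ciliated over basal cells 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.44 with an estimated correlation), and in ciliated minus club 1 rose and 5 fell, also over the list alone (camera adjusted p = 0.0068, and adjusted p = 0.37 with an estimated correlation). The one that was higher in ciliated cells was Sftpc, the surfactant protein C gene, at 8.77 ± 0.58 in ciliated, 5.24 ± 0.04 in basal and 5.37 ± 0.14 in club cells.

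**Figure D2:**
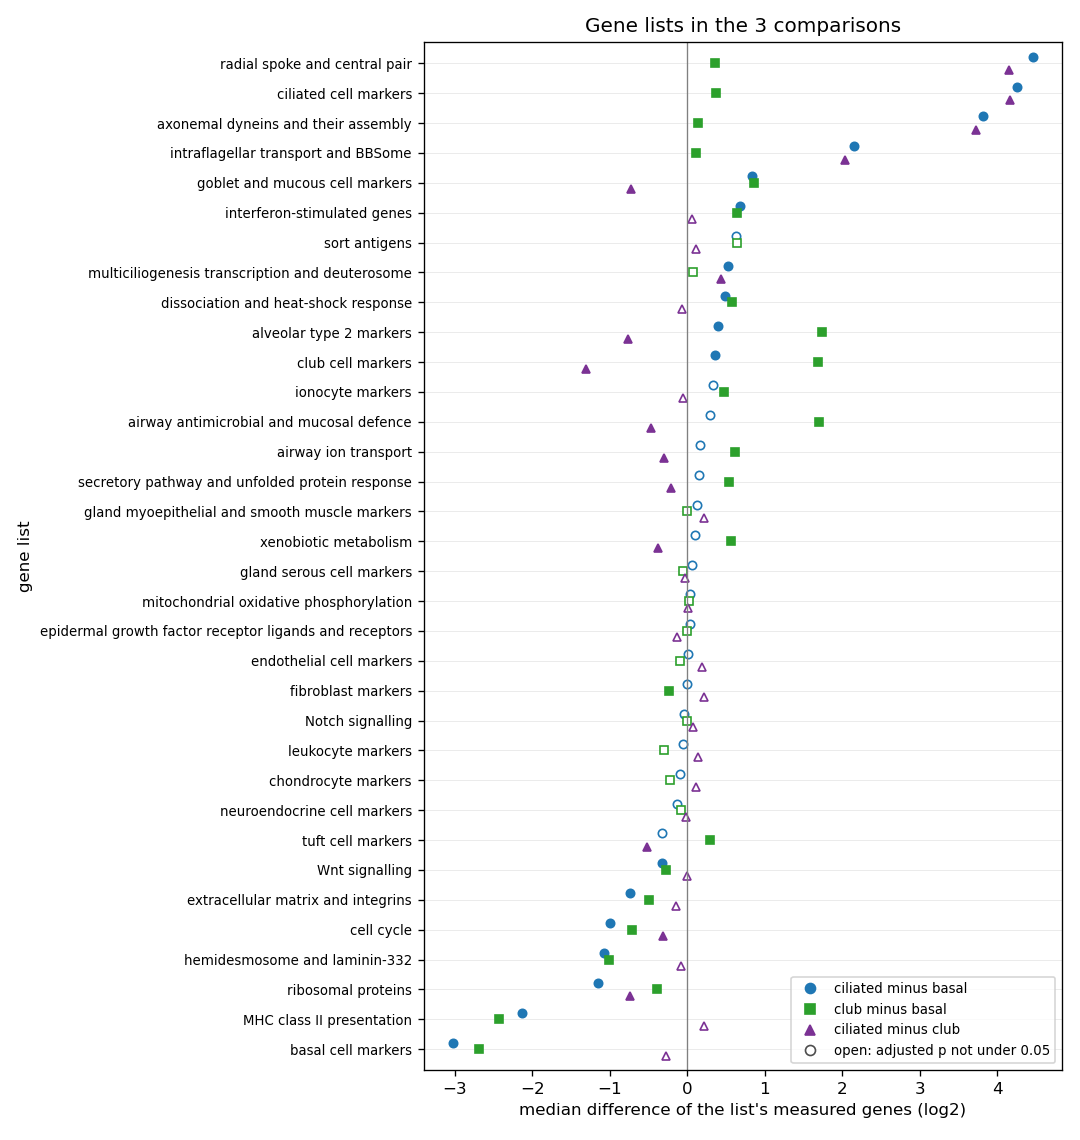
Median log2 difference (horizontal axis) of the members of 34 gene lists in the 3 contrasts, given by circles, squares and triangles, filled where the camera adjusted p was under 0.05 and open elsewhere. The radial spoke, dynein, transport and ciliated marker lists lie furthest to the right in both contrasts with ciliated cells (up to 4.46 for radial spokes), and the basal markers furthest to the left against basal cells (-3.03 and -2.69).

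The authors' deposited table of 50 genes with high basal z-scores was compared with the fit. All 50 were in the per-gene table, with z-scores of at least 1.503. In the limma fit, 29 of them were higher in basal than in ciliated cells and 28 higher than in club cells, with median differences of 0.86 and 0.854 log2 units, and 25 were higher than in both, 20 of these by at least 1 log2 unit. Adjusted over the list alone, 36 and 42 passed. The rule that chose the genes is not given. All of them have a high basal z-score computed on these same samples, so these counts are not independent evidence of their direction. In 17 of the 50 the smaller difference was under 0.5 log2 units.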

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

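All alternatives but the array-set block were chosen before the data were examined. No list or named gene that was called turned direction while still called under any alternative run. The estimated correlation moved the lists called by camera to 0 in all 3 contrasts, although fry called 16, 19 and 14, of which 15, 17 and 13 were also called at the preset correlation. With an estimated correlation camera by construction refers a list to the few residual degrees of freedom of the fit, and at the preset correlation it does not. Stricter thresholds lowered counts by construction: at least 2-fold left 2361 genes in ciliated minus basal and 2062 in ciliated minus club, a smaller difference of at least 2 log2 units left 112 basal, 473 ciliated and 82 club genes, and an adjusted p under 0.01 left 2135, 726 and 1753 genes in ciliated minus basal, club minus basal and ciliated minus club, and 187 club genes. Every probe set tested on its own gave 1047 in club minus basal, and the cause was not tested. A fit of only the 4 arrays compared gave 1050 there, 3264 in ciliated minus basal and 3978 in ciliated minus club. The differences stay the same in these fits, so the counts moved through the estimate of spread and its degrees of freedom, which were not separated. The SD of the log2 difference between replicates was 0.429 for basal, 0.292 for ciliated and 0.317 for club arrays. The main fit pools these spreads, so its p-values may be too small against basal cells and too large in ciliated minus club. The authors' deposited z-scores over 1.5, which involve no test, took in 1566 basal, 2124 ciliated and 1111 club genes, of which 359, 952 and 292 were in the sets above.

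Leaving out 1 array leaves a cell type with a lone array, which is assumed to vary like the others, and fewer degrees of freedom. Counts then ranged from 1907 to 3807 in ciliated minus basal, from 783 to 2534 in club minus basal and from 1587 to 3978 in ciliated minus club. Those that moved by over 1.5 times were ciliated minus basal without ciliated replicate 1 (2196) or 2 (1907), ciliated minus club without ciliated replicate 1 (1732) or 2 (1587) or club replicate 1 (1879), and club minus basal without basal replicate 1 (2534), ciliated replicate 1 (1050) or 2 (1050), or club replicate 1 (783) or 2 (820). The fits without basal replicate 1 and without basal replicate 2 share the same estimate of spread, so they differ only in the basal array kept. Basal replicate 2 lay further from the club arrays. It differed from club replicates 1 and 2 by more than 1 log2 unit in 2161 and 1837 genes, and basal replicate 1 in 1396 and 1534. What part of the rise without basal replicate 1 came from the changed spread was not separated, nor was it tested why the basal arrays differ. Genes above both other types ranged from 251 to 498 for basal, 834 to 1001 for ciliated and 201 to 417 for club cells, and shifted lists from 16 to 17, 18 to 26 and 14 to 16. Of the 421 calls of named genes, 14 to 96 were lost without 1 array, and 1 to 36 under the other alternatives.

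The labels number the arrays 1 and 2 in each cell type without naming a shared animal or batch. Deviations from the group means correlated across genes at 0.0521, 0.265 and 0.26 for the pairs of cell types. With 2 arrays per cell type, the deviations of replicates 1 and 2 are exact opposites. That 6 of 6 arrays correlated best with their own number therefore only restates that these correlations were positive. Whether equal numbers mark a shared source stays open. With the replicate block, 4104, 2024 and 3739 genes passed in ciliated minus basal, club minus basal and ciliated minus club, and 17, 22 and 15 lists shifted. The one list call it ended was intraflagellar transport in club minus basal (adjusted p = 0.066), and 1 of 421 named gene calls was lost. An array-set block, chosen after replicates 2 of ciliated and club cells were seen to share 4 bright probe sets, gave 2746, 1098 and 3029 genes and 18, 22 and 15 lists. Xist was also highest in these arrays, at 9.46 and 10.57. If Xist reflects sex, this block cannot be told apart from it. The array-set block ended the transport call (adjusted p = 0.087) and added the ionocytes in ciliated minus basal (adjusted p = 0.021).

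A mean over the probe sets of a gene was not run, since no table used here pairs them, nor a robust fit of the lists, which camera does not offer. The authors' scores hold no pairwise contrast. Scaling alternatives moved the median difference of all genes by under 0.1 log2 units, and yet turned the balance of higher and lower genes in both contrasts with ciliated cells. In ciliated minus club the share higher in ciliated cells was also 48.6 percent with the replicate block and 49.6 percent without dim genes. It was 48.2 percent in the fit of 4 arrays, which leaving out either basal array repeats. No array gives signal over background, so levels near the floor of the scale set no lower limit on expression.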

Other observations

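Of the tests in this part, the one on fibroblast collagens, the one on 4 abundant liver genes and the comparison of liver genes with genes of similar level were chosen after the result was seen. The gene lists described first were fixed before the data were examined.

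Notch pathway genes were divided among the cell types. The ligands Jag2 and Dll1 were highest in basal cells: Jag2 stood at 11.04 ± 0.03 (SD, n = 2), higher than in ciliated and club cells by 3.04 ± 0.22 and 4.23 ± 0.22 (SE), and Dll1 at 9.44 ± 0.68 against 6.64 ± 0.07 and 6.50 ± 0.15. The receptors Notch2 and Notch3 were highest in club cells (11.25 ± 0.11 and 8.99 ± 0.16), higher than in basal cells by 1.92 ± 0.15 and 1.49 ± 0.17 and than in ciliated cells by 1.28 ± 0.15 and 1.54 ± 0.17. The receptor Notch1, named after its values were seen, was highest in basal cells, at 10.58 ± 0.06 against 8.92 ± 0.10 in ciliated and 8.66 ± 0.08 in club cells. Lfng, a glycosyltransferase that modifies Notch receptors, differed in all contrasts, at 11.51 ± 0.15 in ciliated, 9.13 ± 0.49 in basal and 7.13 ± 0.05 in club cells (limma adjusted p at most 0.0028 for each), and Dtx1 was at 9.29 ± 0.09, 7.08 ± 0.31 and 7.32 ± 0.15. As a list of 25 the pathway did not shift: 4 rose and 4 fell in ciliated minus basal, 3 rose and 5 fell in club minus basal, and 4 rose and 4 fell in ciliated minus club (5 and 5, 3 and 5, and 4 and 5 adjusted over the list alone; camera adjusted p = 0.77, 0.97 and 0.98). In the last contrast the median was 0.0685 while camera's direction was down.

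Wnt genes were on balance lower outside the basal cells. Of 33, 10 fell and 2 rose in ciliated minus basal (13 and 2 adjusted over the list alone; camera adjusted p = 0.0048, and adjusted p = 0.32 with an estimated correlation), and 6 fell and 1 rose in club minus basal (10 and 2 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.21 with an estimated correlation). The ligands Wnt4 and Wnt10a were at 10.40 ± 0.34 and 9.34 ± 0.40 in basal cells, against 8.90 ± 0.01 and 7.59 ± 0.10 in ciliated and 7.96 ± 0.11 and 7.27 ± 0.11 in club cells. Wnt11 ran the other way, at 10.48 ± 0.06 in ciliated, 6.88 ± 0.26 in basal and 6.92 ± 0.01 in club cells, and Lgr6, an R-spondin receptor, was lower in ciliated cells than in basal and club cells by 1.31 ± 0.19 and 1.27 ± 0.19. In ciliated minus club 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.78), with a median of -0.0109 and a mean of 0.0139. Among 15 genes of the epidermal growth factor receptor family, Egfr was at 10.15 ± 0.51 in basal and 8.51 ± 0.21 in ciliated cells, and Erbb4 at 7.74 ± 0.10 in club, 6.35 ± 0.28 in basal and 5.98 ± 0.10 in ciliated cells. That list had 0 up and 2 down, 1 up and 3 down, and 0 up and 1 down (0 and 2, 3 and 4, and 0 and 1 adjusted over the list alone; camera adjusted p = 0.63, 0.67 and 0.44). Its median and mean differed in sign in ciliated minus basal (0.0286 and -0.132) and in club minus basal (-0.000475 and 0.0151). Ion transport genes in ciliated minus basal had 5 up and 2 down of 20 (6 and 2 adjusted over the list alone; camera adjusted p = 0.2).

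The MHC class II genes that were higher in basal than in ciliated and club cells could come from macrophages or dendritic cells in the basal sort. A list of 26 genes of those cells, none of them a class II gene or a member of another list, was higher in basal cells by a median of 0.535 against ciliated and 0.443 against club cells, a shift that fry called against each. Of its members 10 and 5 passed the limma test with the higher level in basal cells, and members that passed the other way were not counted. Cybb and Ly86, named after their values were seen, were higher by 1.47 and 1.40 against ciliated cells. Cytip and Clec10a, also named afterwards, ran the other way there (basal minus ciliated -1.58 and -1.19). Lcp1, Cd14 and Ifi30 had the highest array signal, which does not rank transcripts of different genes, and were at 8.81 or more in all 6 arrays. Cd14 and Ifi30 were higher in basal than in ciliated cells by 1.53 and 0.50. Against club cells Ifi30 was higher in basal cells by 0.375, while Cd14 and Lcp1 were lower (basal minus club -0.29 and -1.26). The EpCAM gate should remove leukocytes, but how well it did so was not tested. Both such cells and class II expression by the basal cells themselves stay open.

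Dcn and Fbln1, higher in basal than in ciliated and club cells, might come from fibroblasts in the basal sort. Against that source, Col1a1, Col1a2 and Col3a1, which fibroblasts express abundantly, differed by at most 0.292 log2 units, and the largest upper 95 percent limit of their basal minus other difference was 0.675. Dcn was higher by 4.87 against ciliated and 4.42 against club cells. Expression of both genes by basal cells stays open as a hypothesis. The gate on EpCAM should remove fibroblasts as well, which was not tested either.

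Alb, the serum albumin gene of the liver, was at 10.48 in club replicate 1 and 6.59 in club replicate 2, and at 6.38 or less elsewhere, and Gc at 7.78 and 4.97 in the club arrays. The gate on EpCAM should remove most hepatocytes, which was not tested. Of 25 other liver genes, 16 had their highest value of the 6 arrays in club replicate 1. From the share among the nearest 200 genes in mean level on each side of each, 2.86 were expected. The median excess of the 25 genes in club replicate 1 over club replicate 2 was 0.496. The genes do not vary independently and the array is a single one, so liver RNA there may be a source but stays open. Club cells in general are argued against, since in club replicate 2 only 5 of the 25 genes (Rbp4 and Trf among them, named after their values were seen) lay above all 4 basal and ciliated arrays. Whether liver RNA could account for the whole rise of Alb (3.90) and Gc (2.81) stays open: Ttr, Fabp1, Serpina3k and Apoh, which were low in every array (6.26 at most), were higher in club replicate 1 by 0.753 at most and 0.0275 at least, while Ahsg, Apoc3, Apoa2 and Serpina1b, also chosen after their values were seen, were higher by 1.72, 1.66, 1.58 and 1.56.

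The following values were chosen after they were seen. Xist, the X-inactivation transcript, was at 7.07 in ciliated replicate 1, 9.46 in ciliated replicate 2 and 10.57 in club replicate 2, and at 5.49 to 5.68 in the other arrays. Both ciliated arrays thus lay above both basal arrays, and the club arrays differed from each other. If Xist reflects the sex of the animals, sex cannot be told apart from cell type in ciliated minus basal. The Y-linked genes Uty (9.11), Ddx3y (9.03) and Eif2s3y (8.83) were highest in club replicate 1, and Kdm5d was at 7.54 in basal replicate 1 and 7.52 in club replicate 1. In club replicate 2, where Xist was highest, Ddx3y and Eif2s3y were at 8.08 and 7.95, their second-highest values. Uty and Kdm5d were at 7.42 and 6.96 there. Eif2s3y was at 7.835 and 7.752 in the ciliated arrays and at 7.844 and 7.676 in the basal arrays. Y-linked levels thus did not fall throughout where Xist was high, and the sex of the animals stays open. Probe sets 10338036, 10338025, 10338004 and 10338035, which carry no gene name here, were higher in replicate 2 than in replicate 1 by 2.48 to 3.44 in ciliated and by 2.06 to 2.81 in club cells, and by 0.312 to 0.749 in basal cells. The taste and tuft cell genes Gnat3, Rgs13, Tas2r143 and Tas2r135 were higher in club replicate 1 than in club replicate 2 by 2.31, 1.87, 1.52 and 1.51. The basal arrays differed in them too: basal replicate 2 minus basal replicate 1 was -0.325, -0.407, -2.12 and -1.87. In club replicate 2, Tas2r143 and Tas2r135 were at 8.54 and 8.13, above all basal and ciliated arrays.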
